A study of Homo sapiens with 12 samples.

How the data were processed

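Total RNA of 2 colon cancer cell lines, SW480 and Caco2, was measured on 12 Illumina bead arrays that each read 47231 probes. Per the labels' protocols, RNA was extracted with Trizol, cleaned with an RNeasy mini kit and DNase I, and amplified into biotinylated cRNA with the Illumina TotalPrep kit. The samples fell into 7 groups by cell line and transfected microRNA, taken from the source and description labels. SW480 had 2 arrays each of control, MIR196B and MIR375 and 1 array of MIR429. Caco2 had 2 arrays each of control and MIR429 and 1 array of MIR196B. The series' design text calls the controls non-transfected, and the sources used here name no mock or scrambled control, so each comparison with a control also holds whatever transfection itself did.

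The deposited scanner table gave for each probe and array a mean bead signal, a linear intensity with the background still in it, and a detection p-value against negative control beads. GenomeStudio 2009.2 is named in the submitters' processing notes, with no further steps stated. The authors' deposited value table held log2 values of 18766 probes. Its 12 columns had the same quantiles, each with a median of 8.99, and each correlated best with its own array of the scanner table. Every probe in it had a detection p under 0.05 on at least 6 arrays, and 0 scanner probes meeting that minimum were missing from it. Whether the authors corrected the background before taking log2 is not given in the sources used here. The scanner table was the starting point, and the value table was used as an alternative.

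Background was corrected and arrays were quantile normalized with neqc in limma 3.58.1 under R 4.3.3, with the negative control distribution inferred from the detection p and an offset of 16, which gave normalized log2 signals. A probe was tested if its detection p was under 0.05 on at least 2 of the 12 arrays, which left 23377 probes. Symbols of the scanner table were brought up to date through a RefSeq gene table of assembly GRCh38.p14, used for names and for which genes contain which small nucleolar RNA. Of all probes, 27036 carried a current symbol, 4626 an older symbol of a single gene, 12245 a symbol kept as deposited, 3270 no symbol, and 54 a symbol turned into a date, which named no gene here. Of the probes tested, 1560 had no usable symbol. The probe with the highest mean over the 12 arrays stood for each gene, which gave 16783 genes. Of these, 12874 had 1 tested probe and 3909 had several, and disagreement among the probes of a named gene is stated.

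All comparisons except the pooled ones were contrasts of 1 limma model with a mean for each of the 7 groups, fitted with lmFit and eBayes over the 12 arrays with 5 residual and 3.95 prior degrees of freedom. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 11 comparisons were the 5 of a microRNA with the control of its line, the difference of the MIR196B and of the MIR429 effect between lines, MIR196B against MIR375 in SW480, the untreated lines against each other, and MIR196B and MIR429 against control over both lines with the cell line as a covariate. The last 2 were fitted to the 7 arrays concerned. Replicate numbers were not used to pair samples. The lone arrays of SW480 MIR429 and Caco2 MIR196B were assumed to vary like the other groups. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

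The arrays, tests, gene lists and naming rule were chosen before the data were examined. The named genes were, for each microRNA against its control, the 10 with the largest fall and the 10 with the largest rise among genes past the threshold whose treated arrays all lay on the same side of all control arrays. Where fewer than 5 passed in a direction, the 5 with the smallest p were named as values. The known targets of the transfected microRNA, the 5 largest differences each way in the other comparisons, and the members with the largest change in a list that passed its test were also named. A gene with a detection p of 0.05 or more on every array of a group has only a bound there. Its difference is given as at least N-fold, from the mean of the brighter group against a floor. A list's median at the bounds sets such genes at their bound, or at 0 where no bound could be had. The floor was, per array, the higher of the lowest normalized signal among detected probes and the gene's own.

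The 20 gene lists were known targets of MIR196B, MIR375 and MIR429, and genes of epithelial cells, mesenchymal cells, apoptosis, the interferon response, the cell cycle, cholesterol synthesis, the integrated stress and unfolded protein response, enterocyte differentiation, Wnt signalling, p53, hypoxia and glycolysis, NF-kB and chemokines, YAP and TEAD, MAPK output, microRNA machinery, ribosomal proteins, and markers of blood, stromal and endothelial cells. The target lists were written from general knowledge and do not come from these samples. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 20 lists of a comparison, with an estimated correlation and with fry as alternatives. Of the lists that passed in any of the 11 comparisons, the known targets of MIR429 in Caco2 with MIR429 was the single call that held with an estimated correlation.

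Fits were tested on simulated data in which 100 of the 16783 genes were changed by a log2 value of 1 and another 100 by a log2 value of 2. Of the former, the fit recovered 43% in the comparison of SW480 MIR196B, 47% for SW480 MIR375, 25% for SW480 MIR429, 57% for Caco2 MIR429 and 28% for Caco2 MIR196B. At a log2 value of 2, the shares were 94%, 91%, 81%, 89% and 86% in the same order. Between 3 and 7 unchanged genes were called. These shares and counts hold for the simulated data alone. On the real arrays, the log2 difference between replicates had an SD of 0.53 for SW480 MIR196B and 0.26 to 0.32 for the other pairs. Whether the simulated noise matched this uneven spread, or any dependence between genes, was not tested. The simulation therefore does not give the recovery or the false calls of the real fits.

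The alternatives were quantile normalization of log2 signal plus 16 without background correction, background correction with median scaling, no filter on detection, detection on all 12 arrays, the authors' value table, the replicate number as a block, the arrays of the compared line alone, an intensity trend in the variance prior, each probe tested by itself, a minimum change of 1.5-fold, and leaving out each array in turn. Fits of every comparison without SW480 MIR196B replicate 2, and a crossed pairing of those replicates, were added after seeing the data. A test of seed sites in 3′ untranslated regions and its alternatives were not run, because no transcript sequences were used here. The chip as a block was not run, because the scanner table names no chip.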

Results

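Gene expression was profiled in SW480 and Caco2, 2 human colon cancer cell lines, after transfection of the microRNAs MIR196B, MIR375 or MIR429, with the stated purpose of finding their target genes. MicroRNAs are short RNAs that pair with messenger RNAs and lower their level or translation. The 12 arrays comprised 2 untreated, 2 MIR196B, 2 MIR375 and 1 MIR429 array of SW480, and 2 untreated, 2 MIR429 and 1 MIR196B array of Caco2. The mean signal per array ranged from 737 to 934 and the median from 164 to 184, and between 37.5% and 41.4% of probes were detected. Each array carried 1 probe named for each of the 3 microRNA genes. None of these was detected on any of the 12 arrays, the lowest detection p on a transfected array being 0.682 for MIR196B, 0.348 for MIR375 and 0.253 for MIR429, so the arrays did not check the transfections.

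Replicates correlated across genes with Pearson r of 0.994 for untreated SW480, 0.993 for untreated Caco2, 0.994 for Caco2 MIR429 and 0.991 for SW480 MIR375. SW480 MIR196B replicate 2 stood apart, with an r of 0.975 to replicate 1. On that array 1751 of 16783 genes lay over 2-fold from the mean of the untreated SW480 arrays. Replicate 1 had 9 such genes, the MIR375 arrays 10 and 195, and the MIR429 array 36. In Caco2 the count was 183 and 223 for MIR429 and 320 for MIR196B. SW480 MIR196B replicate 2 also had the lowest mean signal and the lowest share of detected probes, 737 and 37.5%.

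**Figure D1:**
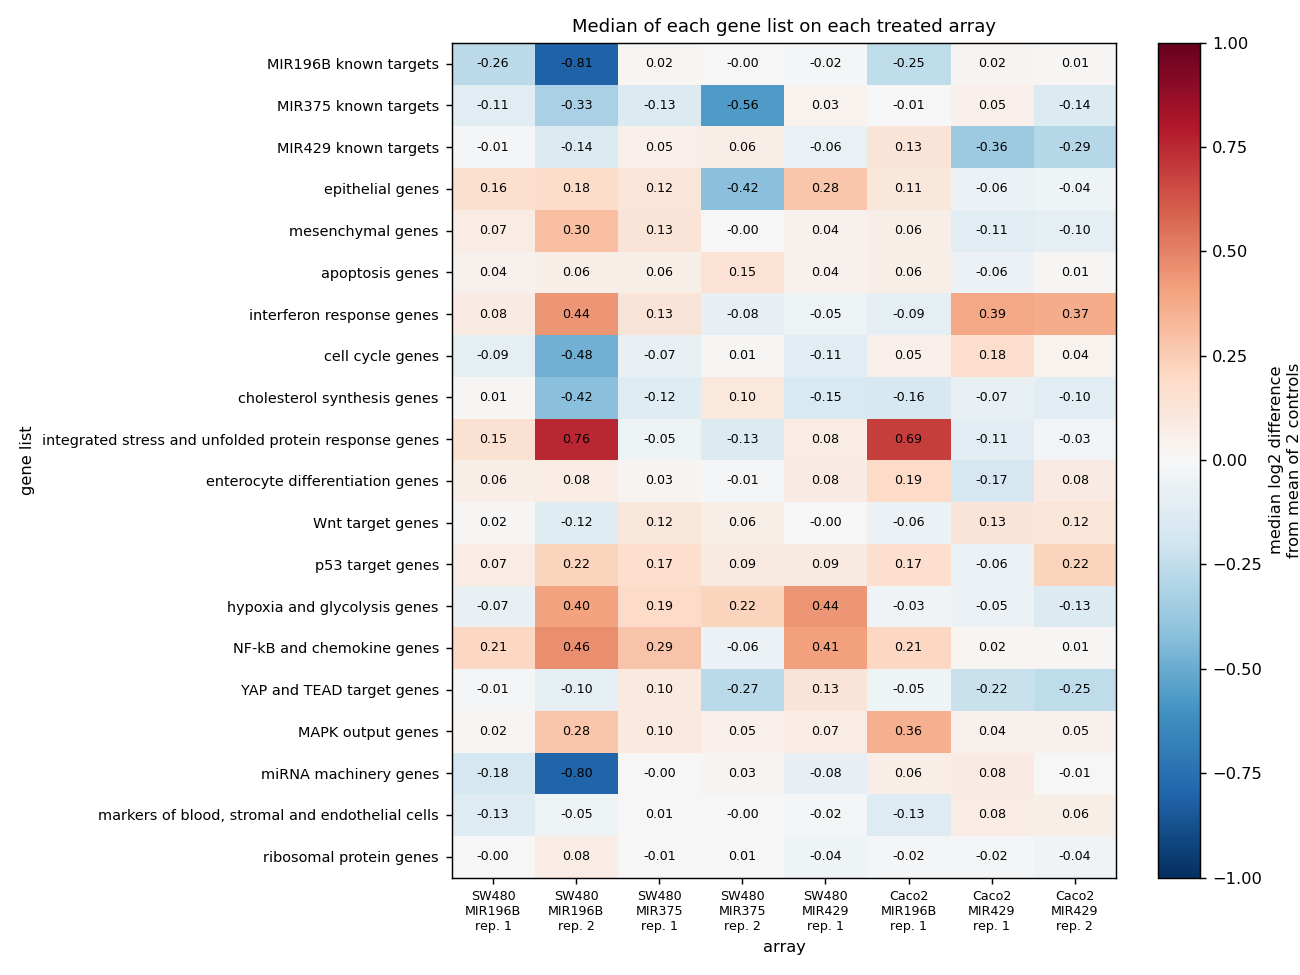
Median log2 difference of each of the 20 gene lists (vertical axis) from the mean of the 2 untreated arrays of the same line, on each of the 8 treated arrays (horizontal axis), as colour and number. The MIR196B known targets lie at -0.26, -0.81 and -0.25 on the MIR196B arrays, and the MIR429 known targets at -0.36 and -0.29 on the Caco2 MIR429 arrays.

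The untreated lines differed in 6674 genes, of which 3520 were higher in SW480 and 3154 higher in Caco2. Caco2, which forms an enterocyte-like layer in culture, held at least 249-fold more SPINK1, a trypsin inhibitor, and at least 183-fold more of the glycine-cleaving enzyme GLDC. APOA1, the main protein of high-density lipoprotein, was lower in SW480 by a log2 difference of -8.78 (SE 0.17, adjusted p = 3.2e-09), and AGR2 and APOA2 were at least 165-fold and 220-fold higher in Caco2, the other AGR2 probe giving -4.49. SW480 held at least 387-fold more DKK4 and at least 217-fold more APCDD1, both Wnt antagonists, at least 165-fold more KRT5 and NELL2, and more LGALS1 by a log2 difference of 7.26 (SE 0.19). Of 18 measured enterocyte differentiation genes, 14 were lower in SW480, with a list median of -1.77, or -1.32 with the 10 genes not above background in a line set at their bound. The median was -0.86 without background correction, -1.09 without a filter and -3.88 in the authors' value table. Among them were CDH17 (-7.28) and, not above background in SW480, VIL1 and APOB (at least 63.0-fold and 60.7-fold lower). The test of the list gave an adjusted p of 4.54e-09, an adjusted p = 0.104 with an estimated correlation, and 0.101 for the genes detected on all 12 arrays.

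Other lists also set the untreated lines apart. Of 19 epithelial genes 13 were lower in SW480, including the adhesion protein CDH1 (-4.65) and, by at least 49.0-fold, RAB25 (list adjusted p = 6.25e-06; adjusted p = 0.254 with an estimated correlation). All 18 cholesterol synthesis genes lay lower in SW480 and 16 passed, with HMGCS1 at -3.32 (list adjusted p = 2.07e-08; adjusted p = 0.254 with an estimated correlation). Of 17 Wnt target genes 13 were higher in SW480 and 3 lower, with NKD1 at 3.24 and AXIN2 at 2.57 (list adjusted p = 0.0033; adjusted p = 0.145 with an estimated correlation). Of 16 MAPK output genes 11 were higher and 1 lower, with EMP1 at 4.43 and ETV5 at 3.66 (list adjusted p = 6.28e-05; adjusted p = 0.137 with an estimated correlation). The markers of blood, stromal and endothelial cells were lower in SW480, 4 of 6 past the test with a median of -1.85 (-1.52 at the bounds), led by LUM (at least 11.5-fold), LYZ (at least 5.79-fold) and CD14 (-2.93) (list adjusted p = 0.00418; adjusted p = 0.142 with an estimated correlation). This call was lost for genes detected on all 12 arrays (adjusted p = 0.196), and the median was -1.02 without background correction and -0.18 without a filter (adjusted p = 0.035). Adjusted over the list alone, the counts lower in SW480 were 14 enterocyte, 14 epithelial, 17 cholesterol and 4 marker genes, and those higher were 13 Wnt and 11 MAPK genes. The known targets of the 3 microRNAs did not pass as lists (adjusted p of 0.394 for MIR196B, 0.449 for MIR375 and 0.277 for MIR429).

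Known MIR429 targets fell as a list in Caco2 with MIR429. MIR429 belongs to the miR-200 family, which holds back the epithelial-to-mesenchymal transition. SEC23A, a coat protein of vesicles leaving the endoplasmic reticulum, fell from 9.58 ± 0.15 to 7.77 ± 0.12 (mean normalized log2 signal ± SD, n = 2 each), a log2 fold change of -1.82 (SE 0.30, adjusted p = 0.0351). With the replicate number as a block in limma, SEC23A had an adjusted p of 0.0665. CFL2, an actin-severing cofilin, fell at least 2.32-fold (adjusted p = 0.00506) and was not above background on the treated arrays. CHMP5, of the endosomal sorting machinery, fell by 1.29 on the log2 scale (SE 0.16, adjusted p = 0.0124), and its other 2 probes gave -1.21 and -0.87. Of the 30 targets measured, 26 lay below 0 and 0 rose, with a median of -0.32, or -0.30 with the 4 targets not above background in a group set at their bound and -0.20 without background correction.

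The 27 other targets did not pass over all genes. Among these, PPM1F lay at -1.23 (adjusted p = 0.0571), ERRFI1 at -1.07 (adjusted p = 0.0678), QKI at -0.80 and MARCKS at -0.75, while FN1 (-0.13), JAG1 (-0.09) and BMI1 (-0.10) lay near 0. Adjusted over the list alone, 8 targets fell. The list passed camera with an adjusted p of 3.09e-07, and with an adjusted p = 0.0271 with an estimated correlation. fry, which tests whether the genes of a list lie, on balance, to one side of 0, gave an adjusted p of 0.00454. The known targets of the other microRNAs did not pass in this comparison, with medians of -0.02 for MIR196B (adjusted p = 0.984) and -0.07 for MIR375 (adjusted p = 0.305). The latter list shares SEC23A and QKI with the MIR429 list.

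**Figure D2:**
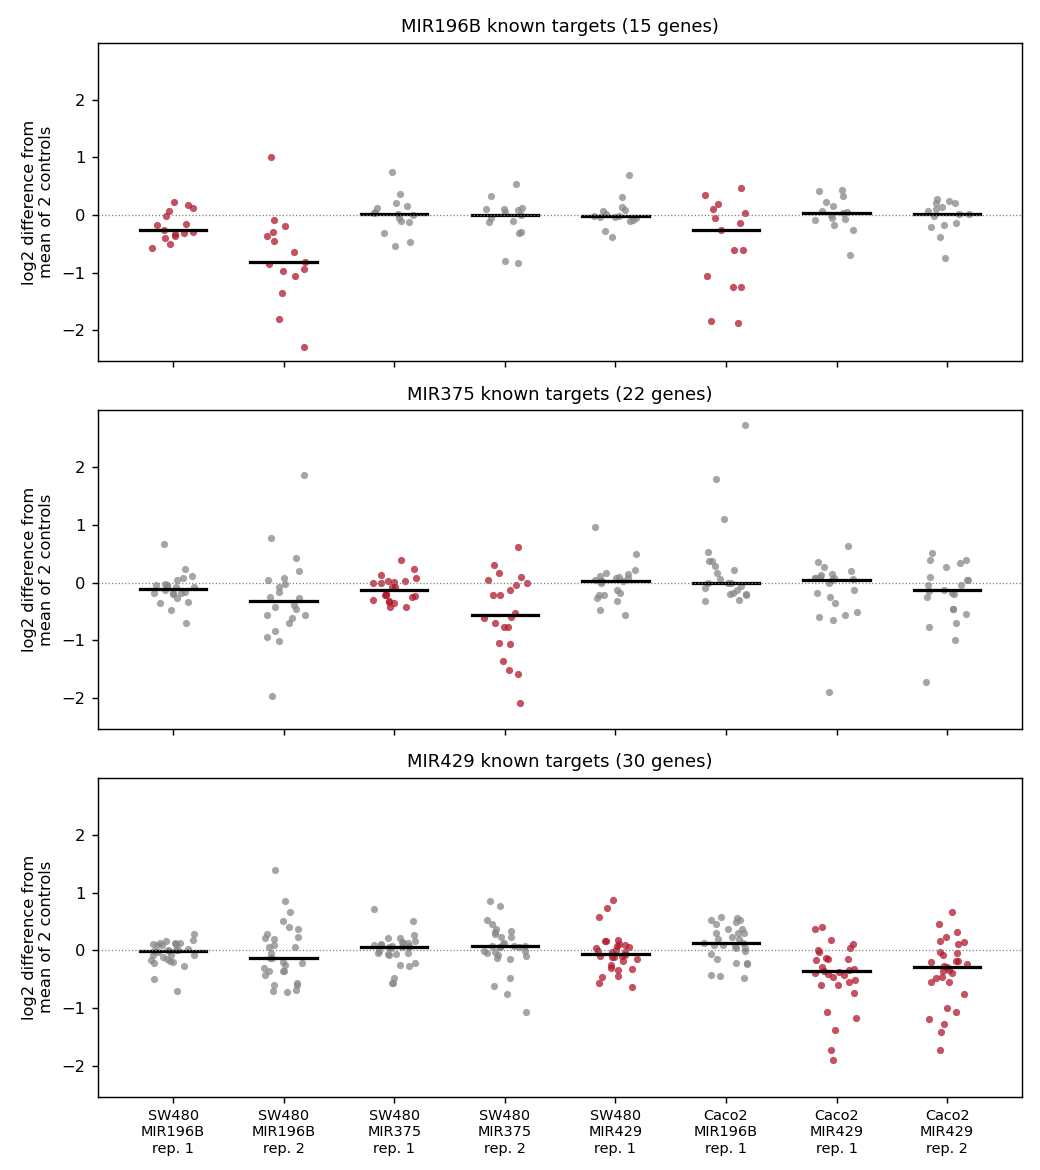
Log2 difference of each known target (vertical axis) from the mean of the 2 untreated arrays of the same line, on each of the 8 treated arrays (horizontal axis), with 1 point per gene and a black bar at the median. Red points are the targets of the transfected microRNA. On the SW480 MIR196B and MIR375 arrays, replicate 2 lies lower than replicate 1, with medians of -0.81 and -0.26 for MIR196B and -0.56 and -0.13 for MIR375.

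In all, 121 genes changed in Caco2 with MIR429, of which 86 fell and 35 rose (60 and 14 with the authors' value table). Of the 10 largest falls 9 were of probes named for H/ACA box small nucleolar RNAs, which guide the conversion of uridine to pseudouridine in ribosomal RNA. Whether these probes, read after RNeasy cleaning and TotalPrep amplification, follow the level of the mature RNAs was not tested. SNORA13 fell by 3.05 on the log2 scale (SE 0.51, adjusted p = 0.0395), SNORA28 by 3.02 (SE 0.48, adjusted p = 0.0321), SNORA62 by 2.69 (SE 0.32, adjusted p = 0.00994) and SNORA6 by 2.54 (SE 0.27, adjusted p = 0.0066). SNORA9 fell at least 6.55-fold, and SNORA38B, SNORA7B, SNORA80E and SNORA63 fell by between 2.20 and 2.55. Over all 65 H/ACA RNAs measured, a group singled out after its values were seen, 63 lay below 0 and 13 passed. The 2 untreated Caco2 arrays themselves differed over these RNAs by a median of 0.47, replicate 1 the higher.

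The remaining gene among the 10 largest falls was ACTA1, a muscle actin, at -2.20 (SE 0.22, adjusted p = 0.00506). Further falls, chosen after their values were seen, included the cargo receptor MCFD2 (-2.04, adjusted p = 0.00158), the collagen-modifying CRTAP (-1.88; other probe -0.54), the actin-bundling FSCN1 (-1.61), the smooth muscle proteins ACTG2 (-1.57) and TAGLN (-1.27), and the transcription factor JUN (-1.46). GAS2, which binds actin filaments and microtubules, rose most, from 6.35 ± 0.03 to 8.49 ± 0.13 (mean ± SD, n = 2 each; log2 fold change 2.14, SE 0.13, adjusted p = 0.00102). ENPP5 rose by 2.01 (SE 0.16, adjusted p = 0.00279), the organic anion transporter SLC22A11 by 1.77 and ODAM by 1.71. Coagulation factor F5 (1.29) and the retinol dehydrogenase RDH5 (1.28) rose, as did C9orf152 and ACOT12, by at least 2.63-fold and 1.77-fold. BTN3A2 rose at least 1.67-fold by its brighter probe while its other probe gave -0.06. AKR1C2 rose by 1.38, but its other probe gave 0.18 and its family members have very similar sequences.

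**Figure D3:**
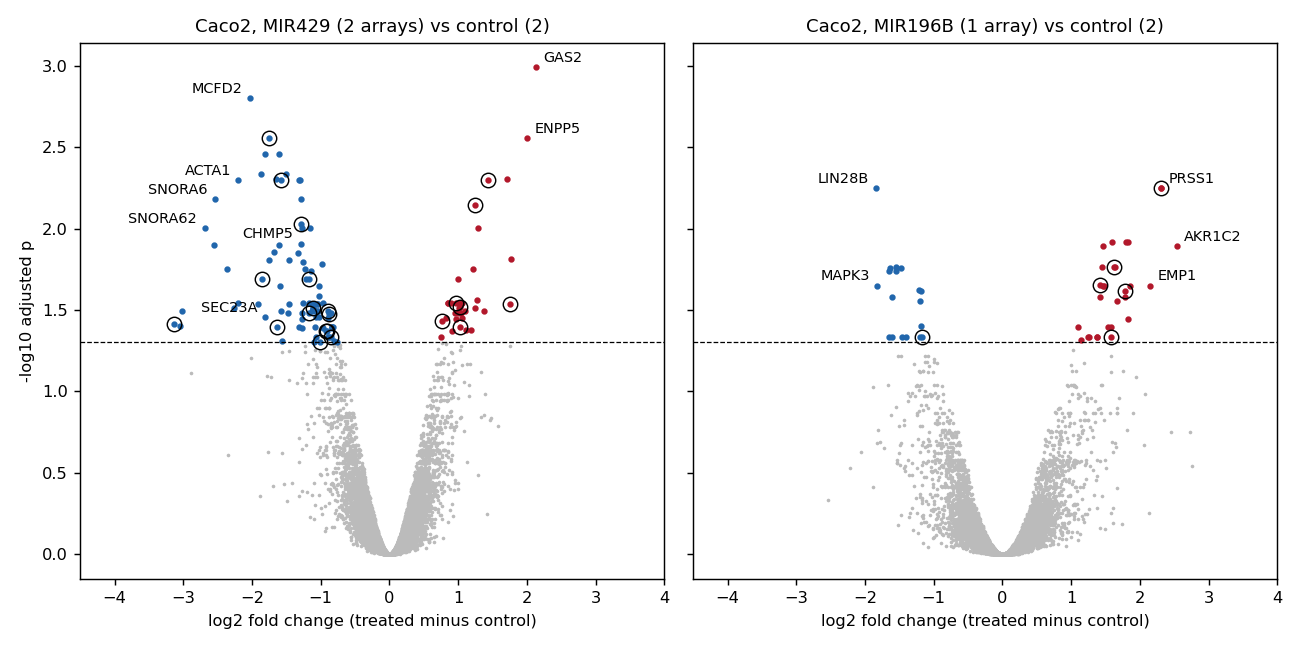
Log2 fold change (horizontal axis) against -log10 of the adjusted p (vertical axis) of 16783 genes in Caco2 with MIR429 and with MIR196B. Red and blue points are genes that rose (35 and 29) and fell (86 and 18), the dashed line is an adjusted p of 0.05, and circles mark genes not above background in 1 group, drawn at their fitted fold change (the circled ANXA4 lies on PRSS1).

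Interferon response genes lay higher in Caco2 with MIR429, 18 of 22 above 0 with a median of 0.33 (0.22 at the bounds), though none passed by itself. HERC5 (0.77), IFIT2 (0.75) and IFIT1 (0.75) had the largest values, and 2 genes rose adjusted over the list alone. The list's adjusted p was 7.05e-05, and the adjusted p = 0.462 with an estimated correlation. YAP and TEAD target genes lay lower, 16 of 21 below 0 with a median of -0.29 (-0.12 at the bounds; -0.15 without untreated replicate 1 or 2, -0.14 without background correction and -0.12 in the authors' value table). Of these FJX1 fell by 1.05 (adjusted p = 0.0321), also when adjusted over the list alone, and CCN1 (-0.69) and F3 (-0.61) did not pass. The list's adjusted p was 0.00414, and the adjusted p = 0.462 with an estimated correlation. The other 17 lists did not pass, with adjusted p of 0.256 to 0.984. Among these the mesenchymal list had a median of -0.06 and 1 fall, TAGLN, and the epithelial list a median of -0.02.

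The count of 121 rested on the pooled spread of both lines. With only the 5 Caco2 arrays in the fit it was 0, and without an array it was 16 (untreated replicate 1), 27 (untreated replicate 2), 13 (MIR429 replicate 1) or 7 (MIR429 replicate 2), while without SW480 MIR196B replicate 2, a setting added after seeing the data, it was 304 and held all 121. GAS2, ENPP5, MCFD2 and the list of MIR429 targets passed in all 4 fits that left out a Caco2 array, while without untreated replicate 1, untreated replicate 2, MIR429 replicate 1 and MIR429 replicate 2 the adjusted p was 0.232, 0.182, 0.269 and 0.235 for SEC23A (0.0636 without a filter), 0.0644, 0.109, 0.118 and 0.115 for CHMP5, and 0.0394, 0.0544, 0.0567 and 0.0446 for CFL2.

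**Figure D4:**
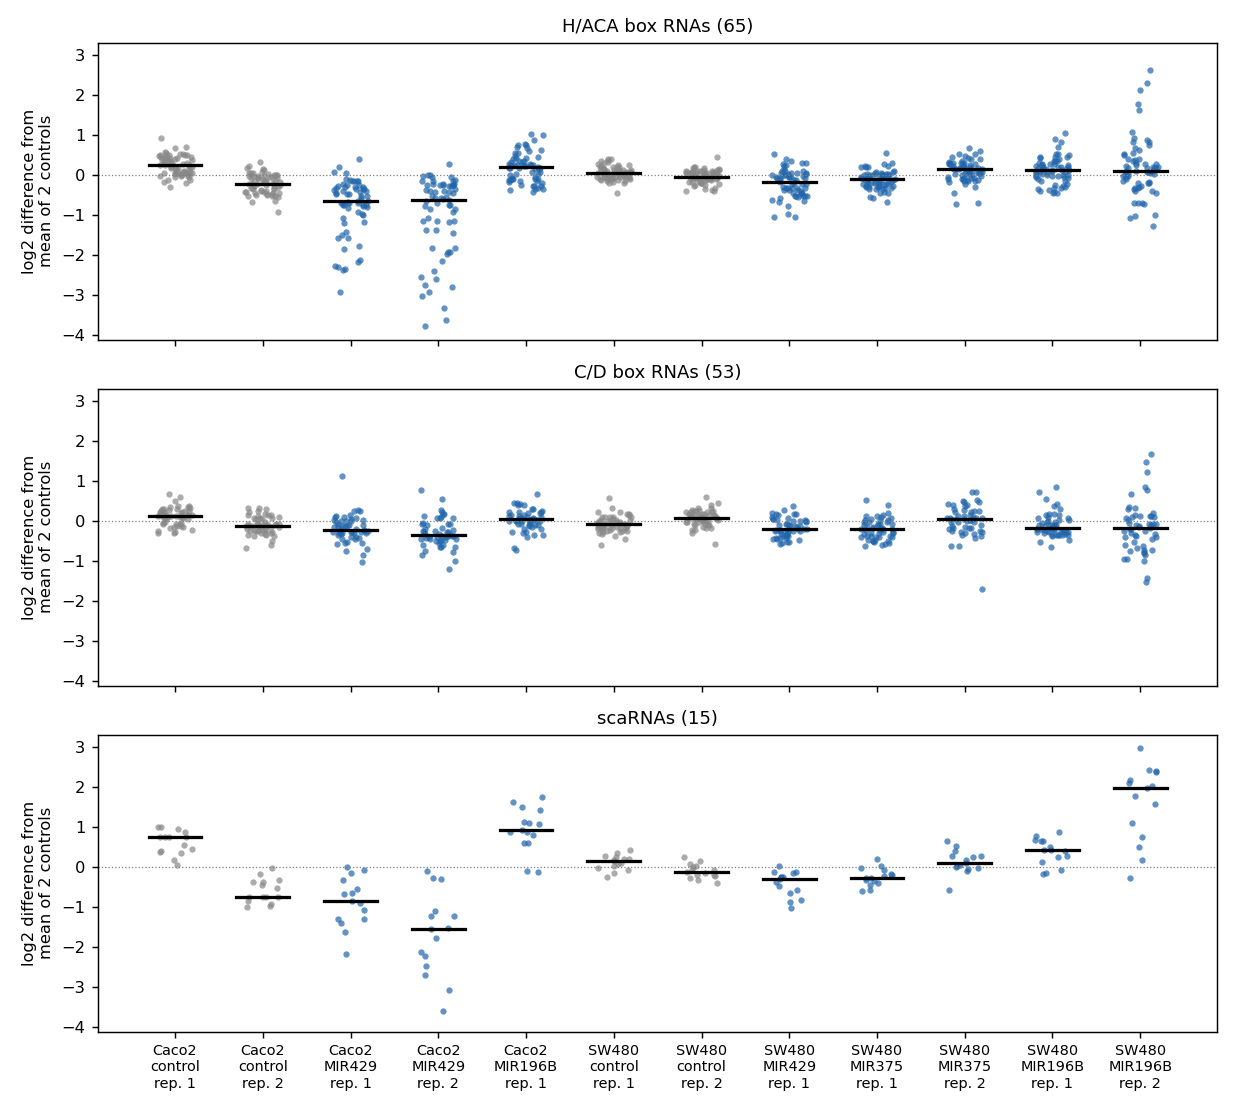
Log2 difference of each small nucleolar or small Cajal body RNA (vertical axis) from the mean of the 2 untreated arrays of the same line, on each of the 12 arrays (horizontal axis), with 1 point per RNA and a black bar at the median of each class. The 65 H/ACA RNAs have medians of -0.67 and -0.62 on the Caco2 MIR429 arrays, and the 15 small Cajal body RNAs (scaRNAs) a median of 1.96 on SW480 MIR196B replicate 2.

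LIN28B, a known MIR196B target that blocks maturation of let-7 microRNAs, fell in Caco2 with MIR196B. It had the largest fall of the genes that passed, from 10.65 ± 0.04 (mean ± SD, n = 2) to 8.81 on the single MIR196B array, a log2 fold change of -1.84 (SE 0.16, adjusted p = 0.00567). The HOX transcription factors on the list, which set position along the body axis, did not pass over all genes: HOXB7 lay at -1.88 (adjusted p = 0.0939), HOXA9 at -1.25 (adjusted p = 0.0913) and HOXC8 at -1.25 (adjusted p = 0.553), while HOXA10 lay at 0.47. Of 15 targets measured 10 lay below 0, with a median of -0.25 (-0.38 and -0.42 without untreated replicate 1 and 2, -0.10 without a filter, -0.16 without background correction, -0.12 with median scaling, -0.11 in the authors' value table and -0.61 for those detected on all 12 arrays), and 6 fell adjusted over the list alone. The list's adjusted p was 4.58e-05, and the adjusted p = 0.4 with an estimated correlation. In the same cells the MIR429 and MIR375 lists had medians of 0.13 (adjusted p = 0.221) and -0.01 (mean 0.27, adjusted p = 0.293). RASD1, listed as a MIR375 target, rose.

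In all, 47 genes changed in Caco2 with MIR196B, of which 18 fell and 29 rose. The balance depended on the processing, with 7 falls and 51 rises under median scaling, 35 and 36 without background correction, 33 and 29 with an intensity trend and 11 and 8 with the authors' value table. The MAP kinase MAPK3 fell by 1.82 (SE 0.24, adjusted p = 0.0224), and its other probe gave -1.88. GCNT2 (-1.66), the sulfotransferase SULT2A1 (-1.64), the coatomer subunit COPZ1 (-1.61), the sorting nexin SNX17 (-1.55), APOBEC2 (-1.55) and the magnesium channel TRPM6 (-1.47) also fell. TPD52 fell by 1.65 and the natriuretic peptide receptor NPR2 by 1.60, with smaller values of -0.56 and -0.75 from their other probes. The trypsinogen PRSS1 rose by 2.31 (SE 0.20, adjusted p = 0.00567), ANXA4 at least 3.82-fold (adjusted p = 0.00567), EMP1 by 2.15 (SE 0.27, adjusted p = 0.0224) and the collagenase MMP1 by 1.85. ITIH2, REG1A, GPC5 and RASD1 rose by between 1.79 and 1.83, and CSTL1 rose at least 2.28-fold. AKR1C2 rose by 2.54 by its brighter probe, and its other probe gave -0.19. Further rises, chosen after their values were seen, were the carcinoembryonic antigens CEACAM5 (1.67) and CEACAM6 (1.48) and REG4 (1.45).

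Genes of the integrated stress and unfolded protein response lay higher with MIR196B in Caco2, 14 of 16 above 0 with a median of 0.69 (0.68 at the bounds). DDIT4 lay at 2.46, the asparagine synthetase ASNS at 1.60, and CHAC1 and SESN2 were at least 1.58-fold and 2.16-fold higher. None passed over all genes and 4 rose adjusted over the list alone (list adjusted p = 8.9e-07; adjusted p = 0.4 with an estimated correlation). MAPK output genes lay higher, 14 of 16 above 0 with a median of 0.36. EMP1 rose, DUSP5 (0.98) and ETV4 (0.73) did not pass over all genes, and 4 rose adjusted over the list alone (list adjusted p = 4.58e-05; adjusted p = 0.244 with an estimated correlation). Of 13 NF-kB and chemokine genes 10 lay above 0, led by CXCL8 (1.32) and RELB (0.98), and 0 rose adjusted over the list alone (list adjusted p = 0.00763; adjusted p = 0.468 with an estimated correlation). The median of this list was 0.21, with an adjusted p of 0.0513 without untreated replicate 1, and 0.47 (adjusted p = 0.00289) without untreated replicate 2, 0.35 with median scaling and 0.58 for genes detected on all 12 arrays. With the replicate number as a block the NF-kB median was 0.13 and that call was lost. The other 16 lists did not pass, with adjusted p of 0.192 to 0.964.

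The single MIR196B array was assumed to vary like the other groups, and the count of 47 was 0 with only the Caco2 arrays, 1 and 0 without untreated replicate 1 and 2, and 259 without SW480 MIR196B replicate 2, a setting added after seeing the data that held all 47. LIN28B passed in 6 of 7 other alternatives and in neither fit without an untreated array (adjusted p = 0.0651 and 0.0732).

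In Caco2, 10 genes changed with each of MIR196B and MIR429, and 8 of these rose with both: AKR1C2, AKR1C3, CLRN3, CYP2J2, ENPP5, GAS2, MEP1A and RNF183. CREG2 fell with both. If the 2 sets of calls were independent, 0.06 genes would be called higher with both and 0.09 lower. The call of GAS2 with MIR196B was lost without background correction (log2 fold change 0.52), with an intensity trend and with the replicate number as a block. It was also lost with only the Caco2 arrays and without either untreated array. GPC5, a heparan sulfate proteoglycan, rose with MIR196B and fell by 1.27 with MIR429. Over all genes the fold changes had a Pearson r of 0.09, against 0.41 in simulations of unchanged groups set against the same controls, and a covariance of 0.00982 against 0.0303. The spread of the untreated arrays alone gave a covariance of 0.0214. Both comparisons used the same untreated arrays, which can by itself give shared changes. With each microRNA set against a different one of these arrays, a test added after seeing the data, r was -0.00244 and -0.16 over the 2 ways.

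In SW480 with MIR196B, 14 of the 15 known targets lay below 0, with a median of -0.48 (-0.45 at the bounds). HOXC8 lay at -1.43 (8.63 ± 1.21 against 10.06 ± 0.13, mean ± SD, n = 2 each; adjusted p = 0.279), the death receptor FAS at -0.99 (other probe -0.14), HOXA9 at -0.79 (SE 0.19), RDX at -0.60 and HOXB8 at -0.59. LIN28B was not above background in either group. None fell over all genes, and 1 fell adjusted over the list alone. The list's adjusted p was 0.000248, and the adjusted p = 0.709 with an estimated correlation. Its median was -0.26 on replicate 1 and -0.81 on replicate 2.

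Other lists lay apart in SW480 with MIR196B, mostly through replicate 2. The cell cycle genes had a median of -0.32 (-0.25 at the bounds; -0.09 and -0.48 on the 2 arrays), with 23 of 25 below 0, MKI67 at -1.63 and TOP2A at -1.11 (list adjusted p = 0.000248; adjusted p = 0.709 with an estimated correlation). The stress response genes had a median of 0.43 (0.35 at the bounds; 0.15 and 0.76 on the 2 arrays), with TRIB3 at 1.36 and DDIT4 at 1.22 (adjusted p = 0.000248; adjusted p = 0.709 with an estimated correlation). The microRNA machinery genes had a median of -0.49 (-0.18 and -0.80), with DICER1, which cuts microRNA precursors, at -1.26 and TNRC6B at -0.99 (adjusted p = 0.00959; adjusted p = 0.709 with an estimated correlation). The interferon genes had a median of 0.20 (0.08 and 0.44; 0.13 without background correction, 0.36 for genes detected on all 12 arrays), with IFI27 at 0.86 and 2 rises adjusted over the list alone (adjusted p = 0.0211; adjusted p = 0.709 with an estimated correlation). The MIR375 targets had a median of -0.27 (-0.11 and -0.33), with EGFR at -0.65 (other probe 0.10) (adjusted p = 0.038; adjusted p = 0.709 with an estimated correlation). Except for the interferon genes, none of these lists had a member past the test adjusted over the list alone. Without replicate 2 the interferon, microRNA machinery and MIR375 target lists each had an adjusted p of 0.118, and the MIR375 targets had 0.104 without replicate 1, 0.0632 without untreated replicate 2, 0.0535 with median scaling, 0.134 for genes detected on all 12 arrays and 0.0638 with the authors' value table. The other 14 lists did not pass, with adjusted p of 0.0512 to 0.827.

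limma called 0 single genes for MIR196B in SW480, where 2992 had an unadjusted p under 0.05. The smallest p of the genes that lay lower belonged to NPAT (at least 1.09-fold), ZNF488 (-1.09), LOC650436 (not above background with MIR196B), SETD1A (-0.85) and SSX2IP (-0.88). Of those that lay higher it belonged to HOMER3 (at least 2.07-fold), CHMP6 (0.97), MPP2 (0.77), CFAP300 (at least 2.02-fold; other probe 0.47) and C6orf126 (1.53), all 10 with an adjusted p of 0.279. Every alternative with both MIR196B arrays gave 0, as did the fit without replicate 2. Without replicate 1 the count was 4849, from replicate 2 alone, assumed to vary like the other groups.

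In SW480 with MIR375, 17 of the 22 known targets lay below 0, with a median of -0.24 (-0.19 at the bounds, -0.12 without a filter). CCN2, a matrix protein induced by YAP1, lay at -1.25 (SE 0.42; other probe -0.92), YAP1 itself at -0.91 (SE 0.34), the lactate dehydrogenase LDHB at -0.84 (SE 0.28), MTDH at -0.69 and MTPN at -0.56, while PDPK1 (0.02) and ATG7 (-0.04) lay near 0. RBPJ lay at -0.78 with its other probe at 0.02. None fell over all genes or adjusted over the list alone. The list's adjusted p was 5.4e-05, and the adjusted p = 0.916 with an estimated correlation. The median was -0.13 on replicate 1 and -0.56 on replicate 2. Hypoxia and glycolysis genes lay higher, 14 of 15 above 0 with a median of 0.19 (0.09 without background correction and in the authors' value table), led by CA9 (0.80) and ADM (0.43), and 0 rose adjusted over the list alone (list adjusted p = 0.0162; adjusted p = 0.916 with an estimated correlation). Without untreated replicate 1 the hypoxia list had a median of 0.08 (adjusted p = 0.56), and without MIR375 replicate 1 a median of 0.22 (adjusted p = 0.221). The other 18 lists did not pass, with adjusted p of 0.191 to 0.957.

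limma called 0 single genes for MIR375, where 660 had an unadjusted p under 0.05, and every alternative with both MIR375 arrays gave 0. Without replicate 1 it called 5. The smallest p of the genes that lay higher belonged to ENPP5 (0.99), CAMK2N2 (0.99), the mucin MUC16 (0.77), UPK1A (0.90) and ADGRG6 (at least 1.45-fold). Of those that lay lower it belonged to CLEC9A (not above background with MIR375), DIRAS2 (-0.66), MGC15763 (-0.66), LOC650251 (at least 1.26-fold) and LOC645197 (at least 1.18-fold; other probe 0.29), all 10 with an adjusted p of 1.

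In SW480 the known MIR429 targets had a median of -0.06 with MIR429, 18 of 30 below 0 (adjusted p = 0.581). CFL2 was at least 1.46-fold lower and not above background on the MIR429 array, SEC23A lay at -0.57 and PPM1F at -0.45, CHMP5 at 0.04 (other probes -0.25 and -0.08) and ERRFI1 at 0.73. None passed over all genes or adjusted over the list alone. Hypoxia and glycolysis genes lay higher, 14 of 15 above 0 with a median of 0.44, among them CA9 (1.20), EGLN3 (1.02) and ADM (0.70) (list adjusted p = 1.11e-05; adjusted p = 0.705 with an estimated correlation). So did NF-kB and chemokine genes, 12 of 13 above 0 with a median of 0.41, led by LTB (0.98) (list adjusted p = 0.0018; adjusted p = 0.705 with an estimated correlation), and epithelial genes, 15 of 19 above 0 with a median of 0.28, led by CDH3 (1.09) and CDH1 (1.05) (list adjusted p = 0.00356; adjusted p = 0.705 with an estimated correlation). In these 3 lists 0 genes rose adjusted over the list alone. The hypoxia and NF-kB medians were 0.27 and 0.24 without background correction, 0.26 and 0.22 for genes detected on all 12 arrays, and 0.29 and 0.26 in the authors' value table. The epithelial median was 0.14 with the replicate number as a block. Without untreated replicate 2 the NF-kB list had a median of 0.20 (adjusted p = 0.464) and the epithelial list 0.24 (adjusted p = 0.127), and without untreated replicate 1 the epithelial median was 0.48. The untreated arrays themselves had NF-kB medians of 0.25 and -0.25. The other 17 lists did not pass, with adjusted p of 0.0575 to 0.901.

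limma called 0 single genes for MIR429 in SW480, where 494 had an unadjusted p under 0.05, and every alternative gave 0. The smallest p of the genes that lay higher belonged to ENPP5 (1.28), IGFBP3 (1.28; other probe 1.23), UPK1A (1.17), ADGRG6 (at least 1.74-fold) and FKBP1B (1.16). Of those that lay lower it belonged to MTMR1 (-0.83; other probe -0.15), ZNF689 (-0.88), LOC642616 (at least 1.42-fold), LOC648196 (at least 1.41-fold) and LOC642784 (-0.95), all 10 with an adjusted p of 1. IGFBP3, a binding protein of insulin-like growth factors, rose adjusted over the YAP and TEAD list alone (adjusted p = 0.0105), as it did with MIR375 (0.87, adjusted p = 0.0348). MIR375 and MIR429 in SW480 had fold changes with a Pearson r of 0.40 across genes, against 0.41 in simulations of unchanged groups set against the same controls. The covariance was 0.0219, against 0.0303 in the simulations and 0.0174 from the spread of the untreated arrays alone. Set against different untreated arrays, the 2 microRNAs had an r of 0.00330 and 0.13 over the 2 ways.

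Set directly against MIR375, so that both groups were transfected, the known MIR196B targets lay lower in SW480 with MIR196B, with a median of -0.41 and 6 falls adjusted over the list alone (adjusted p = 0.00769; adjusted p = 0.833 with an estimated correlation). The MIR375 targets had a median of 0.07 (adjusted p = 0.705). Stress response genes were higher by a median of 0.78 with 10 rises adjusted over the list alone (adjusted p = 0.000885), microRNA machinery genes lower by -0.51 with 5 falls (adjusted p = 0.0254) and cell cycle genes lower by -0.29 (adjusted p = 0.0079), each with an adjusted p = 0.833 with an estimated correlation. Without MIR196B replicate 2 the medians were -0.21 for the MIR196B targets (adjusted p = 0.0623), -0.12 for microRNA machinery (0.191), -0.08 for the cell cycle (0.261) and 0.33 for the stress response (0.0119), and without MIR196B replicate 1 they were -0.68, -0.90 and -0.44 for the first 3, while without MIR375 replicate 2 the cell cycle and stress medians were -0.19 and 0.49. For genes detected on all 12 arrays the targets and cell cycle lists each had an adjusted p of 0.0558 and the machinery list 0.132, and with median scaling the targets and machinery medians were -0.63 and -0.79. limma called 0 single genes, 3905 having an unadjusted p under 0.05, and every alternative with all 4 arrays gave 0. The count was 5165 without MIR196B replicate 1 and 27 without MIR375 replicate 1.

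Between lines, limma called 1 gene for the MIR429 difference, GAS2 (adjusted p = 0.0415), among 875 with an unadjusted p under 0.05. GAS2 rose in Caco2 and was detected on 0 SW480 arrays, so no effect could be measured in SW480 and the fitted difference is no measure of size. The call was lost without background correction (adjusted p = 0.0628), with median scaling (0.0666) and with an intensity trend (0.0799). GAS2 was also not called with the replicate number as a block or with each probe tested by itself. It was absent from the genes detected on all 12 arrays and from the authors' value table, and so was not tested there. The known MIR429 targets lay lower in Caco2 than in SW480 by a median of 0.33 (adjusted p = 0.000106; adjusted p = 0.0711 with an estimated correlation), 0.20 without background correction and 0.21 in the authors' value table. For MIR196B, limma called 0 genes that differed between lines, 1321 having an unadjusted p under 0.05. The count was 18 without background correction, 3 with median scaling, 8 without a filter, 1594 without SW480 MIR196B replicate 1 and 0 in the other alternatives. The call of GAS2 was lost without each of the 6 arrays of the comparison that could be left out, with an adjusted p of 0.434 and 0.347 without untreated SW480 replicate 1 and 2, 0.119 and 0.231 without untreated Caco2 replicate 1 and 2, and 0.316 and 0.23 without Caco2 MIR429 replicate 1 and 2.

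Across genes, and with no array shared, the fold changes of MIR196B in SW480 and in Caco2 had a Pearson r of 0.24, and those of MIR429 an r of 0.15. Pairs of different microRNAs in different lines had r of -0.05 to 0.08. Genes are not independent replicates, so no p is given. Of the 86 genes that fell with MIR429 in Caco2, 68 lay below 0 in SW480 with MIR429, 45 with MIR375 and 32 with MIR196B. Of the 35 that rose, 22 lay above 0 in SW480 with MIR429, 21 with MIR375 and 22 with MIR196B. Of the 18 that fell with MIR196B in Caco2, 13 lay below 0 in SW480 with MIR196B, 8 with MIR375 and 9 with MIR429, and of the 29 that rose, 18 lay above 0 with MIR196B, 16 with MIR375 and 18 with MIR429.

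Pooled over both lines, the MIR196B targets had a median of -0.44 (-0.24 without SW480 MIR196B replicate 2, -0.29 without background correction) with 14 of 15 below 0 and 6 falls adjusted over the list alone (adjusted p = 7.07e-06; adjusted p = 0.534 with an estimated correlation). The MIR429 targets had a median of -0.22 (-0.12 without background correction, -0.14 without a filter and in the authors' value table) with 24 of 30 below 0 and 4 falls (adjusted p = 0.000125; adjusted p = 0.767 with an estimated correlation). Stress response genes lay higher with MIR196B, by a median of 0.57 and with 10 rises adjusted over the list alone (adjusted p = 1.13e-07; adjusted p = 0.534 with an estimated correlation). Interferon genes lay higher with MIR429, by a median of 0.28 (0.18 without untreated Caco2 replicate 2, 0.17 without background correction, 0.14 in the authors' value table) and with 2 rises (adjusted p = 0.00161; adjusted p = 0.767 with an estimated correlation). This rise came from Caco2, where the interferon medians were 0.39 and 0.37 on the MIR429 arrays, against -0.05 on SW480 MIR429. In further lists, NF-kB (0.38, adjusted p = 0.00285) and MAPK output genes (0.22, adjusted p = 0.0188) lay higher and cell cycle (-0.13, adjusted p = 0.0101) and cholesterol synthesis genes (-0.18, adjusted p = 0.0209) lower with MIR196B, and cholesterol synthesis genes (-0.11, adjusted p = 0.0169) lower with MIR429. Each was lost with an estimated correlation, with an adjusted p = 0.534 with an estimated correlation for MIR196B and 0.767 for MIR429. The NF-kB list passed whichever array was left out, with a median of 0.19 without untreated SW480 replicate 2, 0.21 without background correction and 0.23 in the authors' value table. The cell cycle list was lost without untreated SW480 replicate 1 (median -0.11, adjusted p = 0.0707) and SW480 MIR196B replicate 2 (-0.02, 0.441), and the MAPK list without untreated Caco2 replicate 1 (0.18, 0.0742) and Caco2 MIR196B (0.11, 0.534). The cholesterol list was lost for MIR196B without untreated SW480 replicate 1 (-0.19, 0.0531), untreated Caco2 replicate 1 (-0.18, 0.0687), SW480 MIR196B replicate 2 (-0.09, 0.228) and Caco2 MIR196B (-0.20, 0.0658), and for MIR429 without untreated Caco2 replicate 1 (-0.06, 0.0714), SW480 MIR429 (-0.15, 0.187) and Caco2 MIR429 replicate 2 (-0.08, 0.0535). The cell cycle median also moved without untreated SW480 replicate 2 (-0.08), untreated Caco2 replicate 2 (-0.20), SW480 MIR196B replicate 1 (-0.21) and Caco2 MIR196B (-0.32).

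No single gene passed in either pooled comparison. limma called 0 single genes for MIR196B, 1812 having an unadjusted p under 0.05, and 27 without SW480 MIR196B replicate 1, with 0 in the other alternatives. For MIR429 it called 0, 2454 having an unadjusted p under 0.05. The MIR429 count was 15 without background correction, 2 with median scaling, 12 with the authors' value table, 27 with an intensity trend, 313 without the SW480 MIR429 array, 1 without untreated Caco2 replicate 2 and 0 in the other alternatives.

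Several lists did not pass in any of the 5 comparisons of a microRNA with its control. The mesenchymal genes had medians between -0.06 and 0.18 (lowest adjusted p = 0.306), the apoptosis genes between -0.01 and 0.10 (0.201), the Wnt target genes between -0.12 and 0.13 (0.393) and the p53 target genes between 0.08 and 0.17 (0.191). Cholesterol synthesis genes lay between -0.20 and -0.02 (0.0575) and enterocyte genes between -0.08 and 0.19 (0.0575). Ribosomal protein genes lay between -0.04 and 0.03 (0.311), and the markers of blood, stromal and endothelial cells between -0.13 and 0.09 (0.293).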

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

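The 3 patterns weighed here were noticed in the data, and the tests of a larger MIR196B effect, of small RNA recovery, of a MIR429 effect shared by both lines and of a wrong label were chosen or altered only after the result was seen.

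The effect of MIR429 differed between SW480 and Caco2, by the test of the difference itself, for 1 gene and 7 lists, with values given as SW480 minus Caco2. GAS2 had a fitted difference of -2.19 (adjusted p = 0.0415), but it was detected on 0 SW480 arrays, so that value is no measure of how far the effects differ. The known MIR429 targets differed by a median of 0.33 (adjusted p = 0.000106; adjusted p = 0.0711 with an estimated correlation), YAP and TEAD target genes by 0.34 (0.000507; 0.401 with an estimated correlation), hypoxia and glycolysis genes by 0.31 (0.00215; 0.772) and interferon response genes by -0.28 (0.00215; 0.661). Epithelial genes differed by 0.29 (adjusted p = 0.0113; 0.772 with an estimated correlation), enterocyte differentiation genes by 0.27 (0.0455; 0.661) and NF-kB and chemokine genes by 0.32 (0.0455; 0.772). The first 4 of these lists passed in all 6 fits without 1 array, the interferon call being lost for genes detected on all 12 arrays (-0.04, adjusted p = 0.684). The hypoxia median was 0.20 without untreated SW480 replicate 1, and the YAP and TEAD median 0.55 and 0.53 without untreated SW480 replicate 2 and Caco2 MIR429 replicate 1. Without background correction and in the authors' value table the MIR429 target median was 0.20 and 0.21 and the YAP and TEAD median 0.21 and 0.20, the latter reaching 0.60 for genes detected on all 12 arrays, and the NF-kB median was 0.21 without background correction. The enterocyte median was -0.01 without Caco2 MIR429 replicate 1 (adjusted p = 0.401), on the other side of 0, 0.14 without untreated SW480 replicate 1 (0.214) and 0.27 without untreated Caco2 replicate 2 (0.105), and the call was also lost without background correction (0.12, 0.0732), with median scaling (0.30, 0.0701), without a filter (0.08, 0.122), for genes detected on all 12 arrays (0.24, 0.367) and with SW480 MIR196B replicate 2 left out of the fit (0.28, 0.0819), a setting added after seeing the data. The NF-kB call was lost without untreated SW480 replicate 2 (0.13, adjusted p = 0.646), untreated Caco2 replicate 2 (0.19, 0.105) and Caco2 MIR429 replicate 1 (0.23, 0.0909), and with a median of 0.22 without a filter (0.122) and for genes detected on all 12 arrays (0.356), and the epithelial call without untreated SW480 replicate 2 (0.27, 0.097). Without untreated SW480 replicate 1 those medians were 0.62 and 0.44. With the replicate number as a block the NF-kB median was 0.28 and that call was lost.

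The effect of MIR196B differed between lines for 5 lists. The medians, SW480 minus Caco2, were -0.34 for MIR375 known targets (adjusted p = 0.00683), 0.25 for interferon response genes (0.0169), -0.28 for cell cycle genes (0.00354), -0.25 for MAPK output genes (0.00683) and -0.35 for microRNA machinery genes (0.0463). With an estimated correlation the adjusted p was 0.626 for the MAPK list and 0.719 for the other 4. Without SW480 MIR196B replicate 2 the medians were -0.26 (adjusted p = 0.051), 0.08 (0.051), -0.22 (0.171), -0.38 (0.00181) and -0.12 (0.331) in that order, and without replicate 1 the interferon, cell cycle and machinery medians were 0.40, -0.52 and -0.88. The MAPK call was lost without SW480 MIR196B replicate 1 (-0.27, adjusted p = 0.158) and untreated Caco2 replicate 1 (-0.38, 0.0562), and the interferon call without the latter (0.22, 0.0789). The machinery call was lost without untreated SW480 replicate 2 (-0.27, adjusted p = 0.0911) and untreated Caco2 replicate 1 (-0.37, 0.0913) and 2 (-0.32, 0.058). The interferon median was 0.13 without untreated SW480 replicate 1, 0.05 with median scaling, 0.06 without a filter, 0.12 without background correction and 0.83 for genes detected on all 12 arrays. With median scaling the other 4 medians were larger, at -0.64, -0.49, -0.55 and -0.67. The MIR375 target median was -0.22 without untreated SW480 replicate 2. For genes detected on all 12 arrays the MIR375 target and machinery lists had an adjusted p of 0.0703 and 0.19. With the replicate number as a block the machinery median was -0.27 and that call was lost. In data outside the gene comparisons, 2 probes with no usable gene symbol passed the threshold in Caco2 with MIR429.

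SW480 MIR196B replicate 2 had 1751 genes over 2-fold from the mean of the untreated SW480 arrays, against 9 on replicate 1. Noise of dim probes was argued against, since 8.87% of the genes of the top quartile by level lay over 2-fold. At most 0.691% of the top quartile did on any other treated SW480 array. The share on replicate 2 was 3.38% in the lowest quartile and 14.0% and 15.5% in the quartiles between, so it did not rise steadily with level. RNA of Caco2 cells was argued against by a Pearson r of -0.0299 with the difference between the lines, across 6674 genes. A larger effect of MIR196B in this replicate may account for part of the pattern, since the median of the known targets lay 0.09% of the way up 10000 random lists of like level (replicate 2 minus replicate 1, -0.56, against an interval of -0.30 to 0.32 for the lists), and the array's r with Caco2 MIR196B was 0.25, against 0.15 for replicate 1 and -0.05 with the Caco2 MIR429 effect. The shift was not particular to these targets. MicroRNA machinery genes lay at -0.18 and -0.80 on replicates 1 and 2, and stress response genes at 0.15 and 0.76. Epithelial (0.16 and 0.18) and apoptosis genes (0.04 and 0.06) moved little. The percentile alone therefore does not single out MIR196B. A difference in how this sample was handled stayed open as well, since the labels name no batch, and no explanation was shown to cover the whole pattern.

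In Caco2 with MIR429, 63 of 65 H/ACA RNAs lay below 0 and 13 fell, 43 of 53 C/D box RNAs lay below 0 with 0 called, and 15 of 15 scaRNAs lay below 0 with 1 fall. A lower RNA level of the host genes was argued against for those measured. Of 15 genes whose span held a called H/ACA RNA, the 11 measured had a median of -0.0878 (-0.34 to 0.51), against -2.36 for the H/ACA RNAs called. Hosts were taken by position without regard to strand, and array signal follows RNA level, which need not follow transcription. Lower transcription of the host genes therefore stayed open. Variation between samples in the recovery or labelling of small RNAs stayed open because its tests went apart: in the first, C/D RNAs of higher level had a median of -0.34 and H/ACA RNAs -0.81 (interval of the difference -1.23 to -0.18, 10000 bootstraps), which went against it, and in another, added after that, the fold change across H/ACA RNAs had an r of -0.60 with the difference between the untreated Caco2 arrays (0.33 across the other genes called lower), which went with it. Across H/ACA RNAs the fold change also had an r of -0.46 with SW480 MIR196B replicate 2 and -0.44 with Caco2 MIR196B. The scaRNAs had medians of -0.85 and -1.56 on the Caco2 MIR429 arrays, 0.92 on Caco2 MIR196B and 1.96 on SW480 MIR196B replicate 2. On the other treated arrays their medians lay between -0.30 and 0.41. These values, which were not part of its tests, show that small RNAs also varied without MIR429. An effect of MIR429 shared by both lines stayed open as well. The H/ACA median in SW480 MIR429 (-0.17) lay at the 0.01 percentile of random lists of like level, but the class lay at an extreme on most treated arrays without MIR429 too, at 0.01 on SW480 MIR375 replicate 1, a condition added after the first run had gone with the explanation, 99.91 on replicate 2, 99.94 on SW480 MIR196B replicate 1 and 100 on Caco2 MIR196B, though not on SW480 MIR196B replicate 2 (68.01). The percentile therefore says little for or against it.

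The known MIR375 targets lay lower on SW480 MIR375 replicate 2 than on replicate 1, by a median of -0.39. A wider spread of all genes on replicate 2 was argued against, since that median lay at the 0.02 percentile of 10000 random lists of like level (interval -0.10 to 0.12). A MIR429 sample labelled as MIR375 replicate 1 stayed open. The targets lay lower on it than on SW480 MIR429, by a median of -0.13 (0.01 percentile). They lay at the 0.11 percentile on the array itself, against 75.9 on SW480 MIR429. Arrays without MIR375 also differed on this list, with medians of -0.11 and -0.33 on SW480 MIR196B and 0.05 and -0.14 on Caco2 MIR429. The test of the targets therefore cannot decide about the label. That test replaced an earlier one whose first clause went with a wrong label and whose second did not: over the 72 other genes lower with MIR429 in Caco2, replicate 1 lay below replicate 2 by -0.10 (-0.12 to -0.03, bootstrap), but at -0.04 itself, not as low as SW480 MIR429 (-0.17). A stronger MIR375 effect in replicate 2 was not tested, and other differences between the samples stayed open, with epithelial genes at -0.62 (0.01 percentile) and an r with SW480 MIR429 of 0.58 for replicate 1 and 0.14 for replicate 2. The MIR375 replicates had an r of 0.34 with each other.

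For the genes changed over both lines, other splits of the 7 arrays into 3 and 4 were counted. With MIR196B the real split gave 0 genes, and all 34 splits counted, the real one among them, gave at least as many. Any split must when the real count is 0, so the count says nothing about chance. The highest other split gave 3581 genes and set the untreated SW480 arrays and MIR196B replicate 1 against SW480 MIR196B replicate 2 and the Caco2 arrays. With the cell line as a covariate, this split compares replicate 2 with the other SW480 arrays. With MIR429 the real split gave 0 genes, 34 of 34 splits gave at least as many, the highest other gave 1, and the count again says nothing about chance.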

How the results depend on the processing

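The fits of every comparison without SW480 MIR196B replicate 2, and a crossed pairing of those replicates, were chosen after seeing the data, and all other alternatives before. The counts for MIR196B, MIR375 and MIR429 in SW480 were 0 under every alternative that kept all arrays. Without background correction, 71 genes changed with MIR196B in Caco2, 18 differed between lines for MIR196B and 0 for MIR429, and 15 changed with MIR429 over both lines. With median scaling the last 3 counts were 3, 0 and 2, and the median of all genes for MIR196B in Caco2 moved from 0.01 to 0.12, with 51 rises and 7 falls there. With no filter, 8 genes differed between lines for MIR196B. With detection on all 12 arrays, 74 genes changed with MIR429 and 2 with MIR196B in Caco2. In that setting 0 differed between lines for MIR429, GAS2 not being among the genes tested. The authors' value table gave 74 and 19 in Caco2, and 12 for MIR429 over both lines. The replicate number as a block gave 54 and 19 in Caco2 and 0 for the MIR429 difference. Deviations of like-numbered replicates correlated across genes with an r of 0.23 between untreated and MIR429 Caco2. In SW480 the r was 0.20 between untreated and MIR375, -0.21 between untreated and MIR196B and -0.04 between MIR196B and MIR375. Between the untreated lines it was 0.05. Using only the arrays of the compared line gave 0 and 0 in Caco2. With an intensity trend the MIR429 difference gave 0 genes and MIR429 over both lines 27, and with each probe tested by itself the MIR429 difference gave 0. Without SW480 MIR196B replicate 2, 304 genes changed with MIR429 and 259 with MIR196B in Caco2, including all 121 and all 47 of the reported fit. A crossed pairing of the SW480 MIR196B replicates gave 0 for MIR196B in SW480.

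Leaving out 1 array of the comparison at a time, the count ranged from 0 to 4849 for MIR196B and from 0 to 5 for MIR375 in SW480, from 7 to 27 for MIR429 and from 0 to 1 for MIR196B in Caco2, from 0 to 1594 for the MIR196B difference between lines, from 0 to 5165 for MIR196B against MIR375, and from 0 to 27 and 0 to 313 for MIR196B and MIR429 over both lines. It was 0 in these fits for MIR429 in SW480 and for the MIR429 difference, and 4857 to 5006 between untreated lines. Without SW480 MIR196B replicate 2, an array of neither comparison, the last 2 counts were 1 and 8114. Where an array is left out of a pair, the other is assumed to vary like the other groups. CDH6, called with MIR429 in Caco2 at -1.47, lay at 0.18 and 0.26 without untreated Caco2 replicate 1 and 2, because the gene's other probe was then the brighter, and at -1.57 and -1.37 without MIR429 replicate 1 and 2. Over called genes, 189 of 697 values without an array stayed past the threshold, 506 kept only their direction and 2 reversed, and under the other alternatives 1157 of 1592 stayed past it and 435 kept only their direction. Over called lists 192 of 233 and 373 of 442 values stayed past the threshold and none of the others passed in the opposite direction, though the enterocyte median for the MIR429 difference changed sign, to -0.01 without Caco2 MIR429 replicate 1. Of 49 list medians, 18 were over 1.5 times smaller and 0 larger without background correction, 10 and 1 with the authors' value table, 2 and 7 with median scaling, 7 and 0 without a filter and 3 and 6 with detection on all 12 arrays. Of the 49 list calls 1, 1, 2, 2 and 11 were lost in that order, and 3 with the replicate number as a block, where 2 medians were over 1.5 times smaller. Where no cause is named, the cause was not tested. The test of seed sites and its alternatives, and the chip as a block, were not run. Signal over background limits the fold of genes not detected in a group to a bound.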

Other observations

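All genes in this part were chosen after their values were seen, and no test was added for them. ENPP5, a phosphodiesterase family member, lay above the untreated arrays of its line on all 8 treated arrays. Its log2 difference was 1.95 and 2.06 on the Caco2 MIR429 arrays and 1.26 on Caco2 MIR196B, where it rose. In SW480 it was 1.28 with MIR429, 1.02 and 0.96 with MIR375, and 0.21 and 0.53 with MIR196B, where it did not pass. UPK1A, a uroplakin of the urothelial surface, lay at 0.92 and 0.88 on the SW480 MIR375 arrays and 1.17 on SW480 MIR429, against 0.09 and 0.06 with MIR196B. The SW480 comparisons shared the same untreated arrays.

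Further genes that fell with MIR429 in Caco2 included the clathrin adaptor subunits AP1S2 (-1.67) and AP1M1 (-0.90) and the cargo exporter CNIH4 (-1.14). The glycosyltransferase MGAT2 (-0.83), the collagen chaperone SERPINH1 (-0.85), the neuronal tubulin TUBB3 (-1.26), the stathmin STMN3 (-1.22) and ODC1 (-1.04), which starts polyamine synthesis, also fell. Rises included CIDEB (1.24), SOSTDC1 (1.22), the mitophagy receptor BNIP3L (1.11) and the alcohol dehydrogenase ADH6 (1.00). With MIR196B in Caco2, the mitochondrial carnitine carrier SLC25A20 (-1.46), DFFA, an inhibitor of the caspase-activated nuclease (-1.40), and E2F5 (-1.22) fell. HOXA13, a HOX gene outside the target list, rose at least 2.11-fold, NOV at least 2.64-fold and FGFBP1 by 1.38.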
